A study of Pinus densiflora with 15 samples.

How the data were processed

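RNA sequencing libraries from 3-year-old seedlings of Pinus densiflora (Japanese red pine) were analysed, 15 in all. Per the labels' protocols, seedlings were sprayed on the foliage with Bacillus subtilis JCK-1398, a culture at an OD600 of 0.8 with Tween 20 at 250 µg/ml, or with water holding the same Tween 20. There were 2 sprays, 1 week apart. Inoculation with the pinewood nematode Bursaphelenchus xylophilus, from a suspension of about 20000 nematodes per ml, followed 1 week later. RNA came from ground needles, libraries were made with a TruSeq kit, and 101-bp paired-end reads came from an Illumina HiSeq instrument, per the labels' protocols. The design text speaks of nematode inoculation of every seedling, whereas the labels mark 2 groups as having no infection and 1 as inoculated with Tween 20 water. Groups followed the labels of the single samples.

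Each library had its own table of gene models, with the scaffold, start and end of each, its read count, its RPKM and its protein sequence. The deposited counts were raw reads counted per gene model, per the file headers. The deposited RPKM values were read counts scaled by gene length and library total, per the file headers, and recomputing them from counts, gene span and library total gave the deposited values within a relative deviation of 3e-06. The span ran from gene start to gene end, introns included, and it exceeded 10 times the coding length in 21.6% of the 51751 models, so RPKM understates such genes. The annotation was the Pita set of PineRefSeq, per the file headers. Its version, and whether its genome is of the sampled species, are not given in the sources used here. BWA, SAMtools, Subread and featureCounts are listed in the submitters' processing notes. Their versions, settings and roles, the treatment of reads that map to several genes and the use of strand are not given in the sources used here. Of the gene models, 4754 encoded a protein identical to that of another model, so reads may be split or lost among copies, and 8352 had no read in any library.

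Counts were the basis of all main tests. The 28624 genes kept by filterByExpr (minimum count 10, minimum total 15) were fitted with edgeR 4.0.16 in R 4.3.3, with TMM scaling and 1 mean per group over all 15 libraries, so that the 5 groups of 3 shared one estimate of the spread per gene. Differences were tested with the quasi-likelihood test, 2-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Unless another tool is named, an adjusted p is from this test. There were 6 comparisons: bacterial against water spray without inoculation; nematode against mock inoculation after the water spray; bacterial against water spray under the nematode; bacterial spray with nematode against mock; the difference between the spray effects with and without nematode; and mock-inoculated against uninoculated seedlings after the water spray. Standard errors of log2 fold changes were derived from the test statistic. A fold against a group with 0 reads is a lower bound set with 3 reads over the whole group. With 1 to 3 reads it is a ratio with an exact binomial interval at 95% that covers counting error only.

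The design fixed before the data were examined held gene lists defined by words in gene names. The tables pair gene IDs with protein sequences and not with names, so those lists could not be used. Instead, 60 families were defined from short conserved protein signatures, after the spread between replicates had been seen and before any test between groups. Some signatures were revised on their number of matches to real and shuffled proteins alone. A family with at least 5 genes past the filter was tested, which left 55, with limma's camera (limma 3.58.1) at its preset correlation of 0.01 and again with an estimated correlation, adjusted over the 55 families. Signatures miss divergent members and can take in other proteins, so family names state what the signature matches. How many families to describe was settled after their values had been seen. Family levels are means over members of log2 CPM. Within families, genes were grouped as near-identical at 95% protein identity over 80% of the shorter protein (BLAST 2.17.0), except in families of more than 400 genes. The named genes follow the rule fixed for data without names: the 2 largest rises and the 2 largest falls per comparison, among genes past the threshold with at least 2 RPKM in the higher group and groups that do not overlap. For the difference of spray effects the condition on overlap was not applied, and the RPKM limit was set on the highest group. This rule leaves all other genes unnamed.

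Alternatives fixed before the data were examined were limma on log2(RPKM + 0.5), with pseudocounts of 0.1 and 1, RPKM rescaled to TPM, with TMM factors or with quantile normalization, with RPKM of at least 1 in 3 libraries; no filter; RPKM of at least 5 in 3 libraries; the replicate number as a block; only the groups compared; robust fitting; DESeq2 1.42.0 with no count filter; a change of at least 1 on the log2 scale; and each library left out in turn. Added after seeing the data were voom with 1 weight per group, total counts and median-ratio scaling, DESeq2 on the genes of the edgeR fit, the mock libraries divided between the comparisons that share them, the log2 limit on the fits of only the groups compared, 1 gene per near-identical group, and further settings for the families. The tests were checked on simulated counts for the 28624 genes, drawn with each group's own spread. The groups compared were given their common mean, with 200 genes changed by 2-fold or 4-fold in each of 3 simulations per comparison. Changed genes were drawn only from those above a minimum expected count, so the recovery rates do not cover genes with fewer reads. Of genes changed 4-fold, 92.7% were recovered for the spray without inoculation, 86.7% for nematode against mock, 84.7% for the spray under the nematode, 87.3% for spray and nematode against mock, 61.7% for the difference of spray effects and 90.7% for mock against uninoculated. Of genes changed 2-fold, 53.7%, 33%, 33.7%, 34.3%, 12% and 43.7% were recovered, in the same order. False calls among 28381 unchanged genes numbered 650 to 733, 0, 0 to 1, 0, 37 to 51 and 155 to 213. A planted family was called in 3 of 3 simulations of each comparison. Simulated genes vary independently, so these simulations do not test the family calls against correlated members. No genome sequence or table of gene names was used here.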

Results

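The series measured needle gene expression in pine seedlings that had or had not received a foliar spray of Bacillus subtilis JCK-1398, a bacterium applied with the aim of inducing systemic acquired resistance, before inoculation with the pinewood nematode, the agent of pine wilt disease. There were 5 groups of 3 libraries: bacterial spray without inoculation, water spray without inoculation, bacterial spray with nematode, water spray with nematode, and water spray with mock inoculation. Total counts per library were 22445796 to 22565408 reads with bacterium and 18805675 to 24218667 with water without inoculation, 21705828 to 22123645 with bacterium and nematode, 16140908 to 22889734 with water and nematode and 18948951 to 27481207 with mock inoculation. Genes are given by ID, since the tables do not pair IDs with names. Nothing in the labels says that replicates were separate seedlings, so all p-values measure only the spread between these libraries, which may be technical.

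Replicates were far closer in some groups than in others. The biological coefficient of variation was 32.7% in the bacterium-sprayed and 44.1% in the water-sprayed uninoculated group. It was 5.58% with bacterium and nematode, 6.34% with water and nematode and 6.04% with mock inoculation. Spearman correlations between replicates were 0.952 to 0.966 and 0.920 to 0.940 in the uninoculated groups, and 0.992 to 0.995 in the 3 inoculated ones. Replicate 3 of the water-sprayed uninoculated group correlated more closely with the 3 bacterium-sprayed uninoculated libraries (0.941 to 0.960) than with its own group (0.934 and 0.920). On the first principal component, with 43.0% of the variance, the 6 uninoculated libraries lay apart from the 9 inoculated ones.

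**Figure D1:**
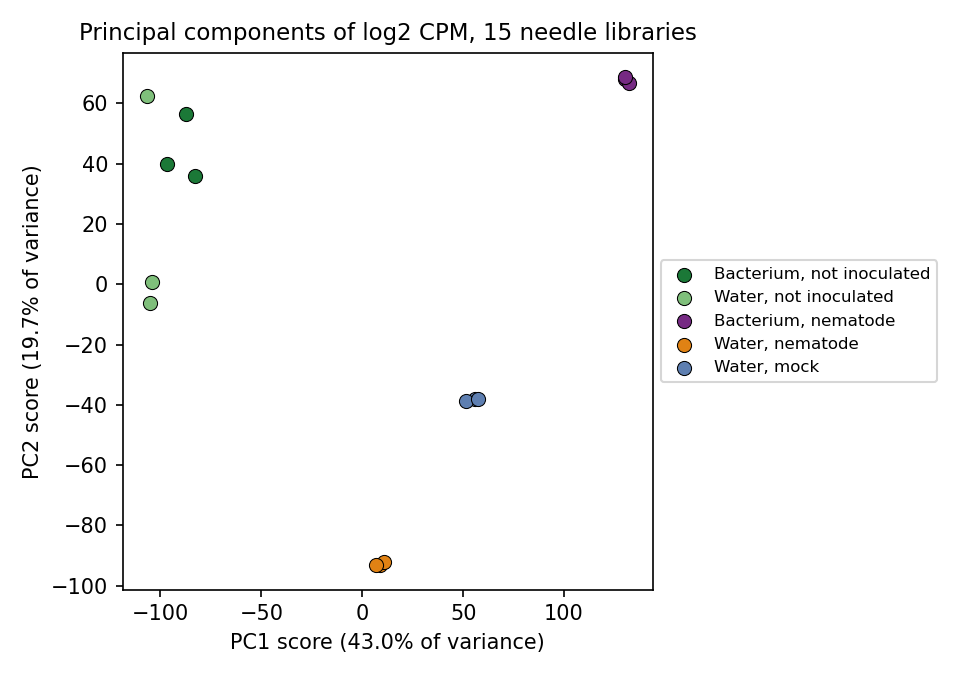
Scores of the 15 libraries on the first and second principal components of log2 CPM, which hold 43.0% and 19.7% of the variance; each point is 1 library and its colour its group. The 3 libraries of each inoculated group nearly coincide, and the 6 uninoculated libraries are spread out at the left.

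Family calls at the preset correlation also arose from groupings other than the labelled ones. Each such grouping mixed the labelled groups unevenly, so part of any labelled difference remained in it. Such groupings therefore do not show how many calls would arise without a labelled difference. Regrouping the 6 libraries of a comparison in the other 9 ways gave 8 to 19 families for the spray without inoculation, where the labelled groups gave 14. It gave 5 to 12 against 15 for nematode against mock, 15 to 24 against 24 for the spray under the nematode, 15 to 21 against 24 for spray and nematode against mock, and 11 to 19 against 16 for mock against uninoculated. With an estimated correlation 3, 2, 3, 6 and 6 of the labelled calls held, in the same order, and 1 of 21 for the difference of spray effects. Those that held are described first in each comparison.

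The bacterial spray was first compared with the water spray in seedlings without inoculation, the state before the nematode. Of 76 class III peroxidase genes (PR-9), secreted enzymes of cell walls and defence, 7 rose and 0 fell, and the family level was 0.61 ± 0.12 log2 CPM (SD, n = 3) against 0.07 ± 0.20 after water. Of 40 lipoxygenase genes, some of which start jasmonate synthesis, 19 fell and 2 rose, at a level of 4.29 ± 0.07 against 4.62 ± 0.19. UDP-glycosyltransferases, which attach sugars to small molecules, rose in 15 and fell in 4 of 143 genes. Adjusted camera p-values with an estimated correlation were 0.0273, 0.0302 and 0.0273. The same water-sprayed libraries are the reference of mock against uninoculated, where these families went in the same directions. The shared libraries may account for part of this. The peroxidase median was 0.50 on the log2 scale, or 0.32 with genes at 0 in a group set to their bound. The lipoxygenase median was -0.59 over genes, but 0.07 over 22 near-identical groups and 0.14 without replicate 2 of the water group, while the test pointed down in both (adjusted p = 0.0288 and 4.91e-10). The glycosyltransferase call ended with 1 gene per near-identical group (adjusted p = 0.231) and without replicate 3 of the water group (adjusted p = 0.0595).

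Other families passed at the preset correlation alone. WRKY transcription factors rose in 8 of 65 genes and fell in 0 (median 0.52, adjusted p = 5.43e-11; adjusted p = 0.160 with an estimated correlation). TIFY proteins, which include repressors of jasmonate signalling, rose in 4 and fell in 1 of 43 genes (median 1.18, or 1.09 at the bounds; adjusted p = 0.373 with an estimated correlation). Chlorophyll a/b-binding proteins of the light-harvesting antennae fell in 7 of 28 genes and rose in 0, with adjusted p = 0.300 with an estimated correlation. Their signature matched 29 gene models and also 6 shuffled proteins, so some of the 28 may be other proteins. Chalcone and stilbene synthases, at the entry to flavonoids and stilbenes, rose in 15 and fell in 3 of 65 genes. Their adjusted p was 0.424 with an estimated correlation and 0.109 without replicate 3 of the water group. For 2-oxoglutarate-dependent oxygenases 40 of 201 genes rose and 5 fell, and for Bet v 1-like proteins (PR-10) 6 of 24 rose and 0 fell. Both calls ended with an estimated correlation (adjusted p = 0.300 and 0.348) and with 1 gene per near-identical group (adjusted p = 0.920 and 0.614), where the medians were -0.08 and -0.09 although the test pointed up. The PR-10 call also ended without replicate 3 of the water group (adjusted p = 0.291), and its median was -0.27 without replicate 2 of the bacterial group.

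In all, 1146 of 28624 genes passed in this comparison, 663 higher and 483 lower after the bacterial spray, and 699 by at least 2-fold. The largest rises were in PITA_04436 (C4637105, 17400 to 18500) and PITA_04570 (scaffold206939, 56421 to 59980). PITA_04436 had 1, 1309 and 284 reads in the 3 bacterium-sprayed libraries and 0 in each water-sprayed one, at least 462.5-fold (adjusted p = 0.0229), and its protein is identical to that of another model. PITA_04570 had 223, 122 and 266 reads against 0, at least 180.5-fold (adjusted p = 5.19e-05). Both genes were read after the water spray in the mock group, at 7.96 ± 0.68 and 3.70 ± 0.12 RPKM (SD, n = 3), where the bacterium-sprayed uninoculated means were 21.4 ± 27.7 and 2.54 ± 0.93. PITA_47475 (C4573215, 14466 to 15899) fell by 4.52 on the log2 scale (SE 0.96, adjusted p = 0.0227), from 4.96 ± 7.08 to 0.217 ± 0.155 RPKM (SD, n = 3), with 456 of its reads after water in replicate 3 and 28 and 21 in the others. PITA_06804 (C4938915, 9452 to 15603) fell by 4.07 (SE 0.50, adjusted p = 0.00200), from 3.67 ± 1.25 to 0.236 ± 0.121 RPKM. The call on PITA_47475 ended without replicate 1 or 2 of the bacterial group (adjusted p = 0.0842 and 0.0610). With limma on log2 RPKM the calls on PITA_47475 and PITA_04436 ended (adjusted p = 0.0833 and 0.0618), as they did with TPM (0.0580 and 0.0531). With voom and 1 weight per group they also ended (adjusted p = 0.294 and 0.863), and so did that on PITA_04570 (adjusted p = 0.0501).

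These calls rested on the spread shared with the inoculated groups. Fitting only the 2 groups compared, edgeR called 0 of 26097 genes (2066 at an unadjusted p under 0.05, smallest adjusted p 0.199), against 1146 in the edgeR fit over all 15 libraries. Over all 15 libraries voom with 1 weight per group called 54, limma on log2 RPKM 948, and DESeq2 2517 on the genes of the edgeR fit and 2496 with no count filter. Simulated groups with their own spread gave 650 to 733 false calls. Without replicate 3 of the water group 6342 genes passed, without replicate 3 of the bacterial group 2039, and without its replicate 1 525. Of the calls 57.9% were higher with TMM, 49.8% with DESeq2 on the same genes, 76.6% with log2 RPKM, 79.7% with TPM and 73.4% with total counts, the last 3 of which moved the median gene by 0.11, 0.16 and 0.10 on the log2 scale.

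Nematode inoculation was compared with mock inoculation after the water spray. Xyloglucan endotransglucosylases, which cut and rejoin wall xyloglucan, fell in 30 of 64 genes and rose in 0, and their level was -0.11 ± 0.09 log2 CPM with nematode and 1.32 ± 0.08 with mock (SD, n = 3). Class III peroxidases fell in 25 and rose in 3 of 76 genes, at 0.24 ± 0.08 against 1.22 ± 0.05. Medians were -1.86 (-1.75 at the bounds) and -0.81 on the log2 scale, and adjusted p-values with an estimated correlation 0.000924 and 0.00544. The 64 xyloglucan genes form 24 near-identical groups, the largest of 22 genes, and the median over groups was -0.77.

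At the preset correlation, HSP90 chaperones rose in 18 of 46 genes and fell in 0 (median 0.82, or 0.22 over 9 near-identical groups; adjusted p = 0.164 with an estimated correlation). AP2/ERF transcription factors, many of them ethylene or stress regulators, fell in 25 and rose in 2 of 61 genes (median -0.85; adjusted p = 0.121 with an estimated correlation). Thaumatin-like proteins (PR-5), a class of antifungal proteins, fell in 13 of 60 and rose in 1, with a median of -0.69, or -0.35 over near-identical groups, and adjusted p = 0.271 with an estimated correlation. Aux/IAA auxin repressors fell in 6 of 21 and rose in 0, with adjusted p = 0.121 with an estimated correlation. Chlorophyll a/b-binding proteins rose in 5 of 28 and fell in 0, with adjusted p = 0.611 with an estimated correlation. Chalcone and stilbene synthases rose in 27 and fell in 1 of 65 genes (median 1.52; adjusted p = 0.623 with an estimated correlation). Their median was -0.23 with TPM, -0.20 with RPKM and TMM, and -0.09 with quantile normalization, and none of these passed (adjusted p = 0.106, 0.106 and 0.332). With 1 gene per near-identical group it was -0.23 (adjusted p = 0.0549), and in all of these settings the test pointed up.

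The nematode comparison called 4757 genes, 1938 higher and 2819 lower with nematode, 2592 of them by at least 2-fold. PITA_08108 (C3906555, 2585 to 3730) and PITA_42480 (C3925741, 2467 to 3612) carry a cytochrome P450 signature, the mark of a large class of oxidising enzymes, and have identical proteins elsewhere, so their reads are uncertain. The proteins of PITA_08108 and PITA_42480 are also near-identical to each other, so these genes may not be separate signals. Both genes had reads with water and nematode, at 26.4 ± 1.83 and 26.2 ± 1.72 RPKM (SD, n = 3), and 0 reads in each library of the other 4 groups. They were at least 736-fold and 731-fold above mock (adjusted p = 7.23e-05 and 6.64e-05). PITA_03609 (scaffold225507, 44244 to 47330) had 6.10 ± 0.35 RPKM with mock and 0 reads with water and nematode, at least 335-fold lower (adjusted p = 4.14e-06). PITA_36003 (C4445181, 716 to 4614) had 3.62 ± 0.14 RPKM with mock and 0 reads with water and nematode, at least 250.5-fold lower (adjusted p = 2.42e-06). Reads of PITA_36003 were missing in that group alone, with 4.56 ± 0.58 RPKM with bacterium and nematode and, without inoculation, 3.01 ± 0.31 after the bacterial and 3.67 ± 1.80 after the water spray. PITA_03609 had 0.502 ± 0.0503 RPKM with bacterium and nematode and, without inoculation, 1, 0 and 2 reads after the bacterial spray and 0 after water. Fitting only the 2 groups compared gave 12027 genes and voom with 1 weight per group 11717, and leaving out any 1 of the 6 libraries gave 2920 to 3094. Of the calls 40.7% were higher with TMM, 29.7% with log2 RPKM and 53.1% with quantile normalization.

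Under the nematode, the bacterial spray was compared with the water spray, the comparison at the centre of the design. Xyloglucan endotransglucosylases rose in 48 and fell in 2 of 64 genes, from -0.11 ± 0.09 to 3.25 ± 0.03 log2 CPM (SD, n = 3). AP2/ERF transcription factors rose in 39 and fell in 5 of 61 genes, from 0.84 ± 0.08 to 2.67 ± 0.07. Class III peroxidases rose in 38 and fell in 4 of 76 genes, from 0.24 ± 0.08 to 1.94 ± 0.03. Adjusted p-values with an estimated correlation were 2.51e-05, 0.00840 and 0.00143. Medians over genes were 4.63, 2.47 and 1.29 on the log2 scale (4.60, 2.35 and 1.29 at the bounds), and over near-identical groups 2.41, 2.41 and 0.99.

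TIFY proteins rose in 32 of 43 genes and fell in 0, from -0.28 ± 0.08 to 3.12 ± 0.06 log2 CPM (median 4.90, or 2.74 over 32 near-identical groups; adjusted p = 0.207 with an estimated correlation). Small heat shock proteins (HSP20), chaperones of unfolded proteins, rose in 26 of 38 and fell in 0 (median 1.21; adjusted p = 0.204 with an estimated correlation). WRKY factors rose in 31 and fell in 11 of 65 genes (median 0.79; adjusted p = 0.265 with an estimated correlation). Chlorophyll a/b-binding proteins fell in 11 of 28 genes and rose in 0 (median -0.55; adjusted p = 0.513 with an estimated correlation). Chalcone and stilbene synthases fell in 35 and rose in 5 of 65 genes (median -1.97, or -0.47 over 11 near-identical groups; adjusted p = 0.522 with an estimated correlation). This last call also ended with TPM (adjusted p = 0.149), RPKM and TMM (0.0766), quantile normalization (0.441) and 1 gene per near-identical group (0.205).

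**Figure D2:**
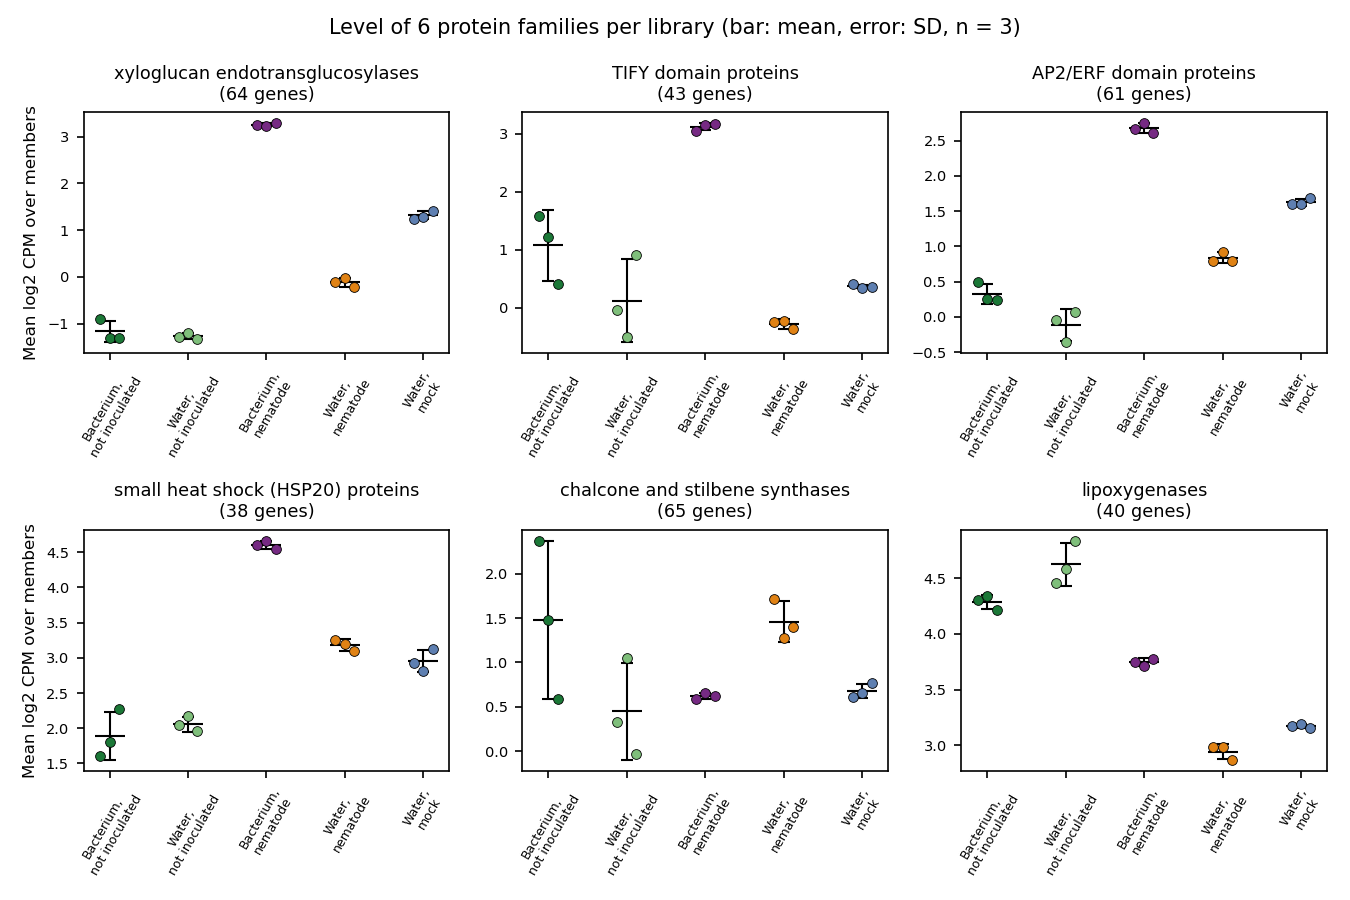
Mean log2 CPM over the members of 6 protein families, on a vertical axis that differs between panels; each point is 1 of the 15 libraries, and bars give the group mean and SD (n = 3). Xyloglucan endotransglucosylases were at 3.25 with bacterium and nematode, -0.11 with water and nematode and 1.32 with mock inoculation.

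A total of 9543 genes passed under the nematode, 5237 higher and 4306 lower after the bacterial spray, 5575 of them by at least 2-fold. PITA_04570 had 57.7 ± 3.92 RPKM (SD, n = 3) after the bacterial spray and 1 read in total after water, a ratio of 11510 with a counting interval from 2065 to 454600 (adjusted p = 1.37e-08). With mock, also after water, it had 259, 301 and 357 reads, or 3.70 ± 0.12 RPKM. PITA_23095 (scaffold8056, 102373 to 103693) had 15.7 ± 0.11 RPKM against 0 reads, at least 388-fold (adjusted p = 0.00531). In the uninoculated libraries this gene had 84, 0 and 78 reads after the bacterial spray and 76, 0 and 102 after water. PITA_08108 and PITA_42480, the near-identical P450 genes with reads in the water and nematode group alone, were at least 663-fold and 659-fold lower after the bacterial spray (adjusted p = 1.19e-05 and 1.04e-05). Fitting only the 2 groups compared gave 15266 genes and voom with 1 weight per group 15214. Of the calls 54.9% were higher with TMM and 37.8% with quantile normalization, which moved the median gene by -0.17 on the log2 scale. Nematode against mock shares the water and nematode libraries, on the other side of the difference, and r across genes was -0.592. Of the calls, 1910 fell there and rose here, against 516 for independent lists, and 1220 did the reverse, against 292. In the same direction were 66 higher and 64 lower, against 355 and 424. Falls of xyloglucan, AP2/ERF and peroxidase genes there and their rises here thus rest in part on the same libraries.

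Fold changes of the spray with and without nematode, which share no library, were weakly related. Across 28624 genes, which are not independent replicates, Pearson's r was 0.147 and Spearman's rho 0.154. Of the calls, 251 were higher in both, where independent lists of those sizes would share 121, 159 were lower in both, against 72.7, and 180 went in opposite directions. Of these, 106 were higher without and lower with nematode, against 99.7, and 74 the reverse, against 88.4. The correlation was 0.0902 and 0.0867 without replicate 1 or 2 of the water-sprayed uninoculated group. It was 0.253 over genes above the median level. The spread in the uninoculated groups, 32.7% and 44.1%, weakens such a correlation. A low r therefore cannot tell a spray effect that differs between the states from noise.

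Bacterium-sprayed seedlings with nematode were also compared with the mock group. Xyloglucan endotransglucosylases rose in 46 and fell in 1 of 64 genes, at 3.25 ± 0.03 against 1.32 ± 0.08 log2 CPM (SD, n = 3). HSP90 rose in 32 of 46 genes and fell in 0, at 3.76 ± 0.02 against 2.34 ± 0.07, and HSP20 in 25 of 38 with 0 lower, at 4.60 ± 0.06 against 2.95 ± 0.16. AP2/ERF factors rose in 28 and fell in 6 of 61 genes, and class III peroxidases rose in 29 and fell in 6 of 76. Adjusted p-values with an estimated correlation were 3.11e-05, 0.0385, 0.0186, 0.0186 and 0.0186, in this order. Medians over genes were 2.62, 2.00, 1.92, 0.78 (0.64 at the bounds) and 0.60 on the log2 scale, and over near-identical groups 0.61, 0.32, 1.92, 0.71 and 0.11. UDP-glycosyltransferases fell in 26 and rose in 14 of 143 genes (median -0.35; adjusted p = 0.0296 with an estimated correlation), a call that ended with quantile normalization (adjusted p = 0.0746).

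Here TIFY proteins rose in 29 and fell in 1 of 43 genes (median 3.12, or 1.39 over near-identical groups; adjusted p = 0.118 with an estimated correlation). WRKY factors rose in 32 and fell in 2 of 65 (median 0.81; adjusted p = 0.0822 with an estimated correlation). Thaumatin-like proteins fell in 23 and rose in 15 of 60 (median -0.67; adjusted p = 0.136 with an estimated correlation). The comparison called 6191 genes, 3505 higher and 2686 lower than mock, 3877 of them by at least 2-fold. PITA_16153 (scaffold66434, 165931 to 170697) had 4.56 ± 0.51 RPKM and PITA_23095 15.7 ± 0.11, against 0 reads with mock, at least 528-fold and 506-fold higher (adjusted p = 0.000241 and 0.00649). PITA_21066 (C4811615, 7245 to 7902) and PITA_47670 (scaffold189648, 222959 to 223616), whose proteins are identical to those of other models, had 24.5 ± 1.43 and 23.9 ± 2.36 RPKM with mock and 0 reads with bacterium and nematode, at least 337-fold and 329-fold lower (adjusted p = 0.0286 and 0.0291). The proteins of PITA_21066 and PITA_47670 are near-identical to each other, so these falls may not be separate signals. In the uninoculated libraries PITA_21066 had 2762, 26 and 202 reads after the bacterial spray and 519, 0 and 455 after water, and PITA_47670 2705, 28 and 190 and 508, 0 and 483. PITA_16153 had 1.38 ± 0.68 RPKM in the uninoculated bacterium-sprayed group and 0.512 ± 0.163 with water and nematode. Leaving out any 1 of the 6 libraries ended the calls on PITA_21066 and PITA_47670 (adjusted p = 0.0532 to 0.0782 and 0.0527 to 0.0791). Fitting only the 2 groups compared gave 13112 genes and voom with 1 weight per group 12806. Of the calls 56.6% were higher with TMM, 46.7% with total counts, 47.6% with TPM and 44.7% with quantile normalization.

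The last comparison and nematode against mock share the mock libraries. Their calls had 395 genes higher in both, against 237 for independent lists, 607 lower in both, against 265, and 884 in opposite directions. Of the last, 160 were higher with water and nematode and lower with bacterium and nematode, against 182, and 724 the reverse, against 345. Across genes r was 0.195 and rho 0.0906. In 20 simulations with the nematode groups at the mock mean, r was 0.460 (0.443 to 0.487) and no list shared a gene, with 0 calls in either. The observed covariance was 0.250 and the simulated one 0.0381, a difference of 0.212. Part of the excess may come from the shared libraries. The mock libraries were also divided between the comparisons in the 6 ways that give 1 to one and 2 to the other, with the lone library assumed to vary like the other groups. Then 52 to 98 genes were higher in both, against 22.9 to 56.0 for independent lists, and 176 to 241 lower in both, against at most 68.9. Of those in opposite directions, 20 to 48 were higher with water and nematode, against 17.3 to 41.2, and 220 to 340 lower, against 66.3 to 98.7. Across genes r was 0.153 to 0.179 and the covariance 0.210 to 0.242. The 1002 genes called in the same direction were 556 to 590 without 1 of the mock libraries and 635 to 648 without 1 of the water and nematode libraries.

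Whether the spray effect differed with the nematode was tested as the difference between the spray effects with and without it. The seedlings without nematode were uninoculated, and no bacterium-sprayed group had mock inoculation. Nematode and inoculation itself therefore cannot be told apart in this difference. Mock and uninoculated seedlings differed in 10860 genes after the water spray. Xyloglucan endotransglucosylases had the larger spray effect under the nematode in 36 of 64 genes and the smaller in 0, with a median difference of 4.28 on the log2 scale (2.89 over near-identical groups; adjusted p = 0.0123 with an estimated correlation). TIFY proteins had 24 genes higher and 1 lower of 43 (median 3.80; adjusted p = 0.464 with an estimated correlation). HSP20 had 20 higher and 1 lower of 38 (median 1.33; adjusted p = 0.0804 with an estimated correlation), and Aux/IAA proteins 8 higher and 0 lower of 21 (median 0.95; adjusted p = 0.0804 with an estimated correlation). Chalcone and stilbene synthases had 38 lower and 1 higher of 65 (median -3.80; adjusted p = 0.425 with an estimated correlation). This median was 0.09 with RPKM and TMM, where the test still pointed down (adjusted p = 0.00271), and the call ended with quantile normalization (adjusted p = 0.0504).

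The difference passed in 5421 genes, 3190 higher and 2231 lower under the nematode. Fitted differences, which set no bound where a group has 0 reads, were 13.69 (SE 3.55, adjusted p = 0.0201) for PITA_13017 (scaffold182054, 20650 to 30266), with a UDP-glycosyltransferase signature, and 12.14 (SE 2.95, adjusted p = 0.0195) for PITA_23095. For PITA_14637 (scaffold39704, 25506 to 26275) and PITA_24346 (super1844, 305169 to 305765) they were -12.73 (SE 1.99, adjusted p = 0.000695) and -12.69 (SE 2.66, adjusted p = 0.00980). PITA_14637 had 70.3 ± 2.36 RPKM with water and nematode and 0.217 ± 0.0917 with bacterium and nematode (SD, n = 3), and without inoculation 0.572 ± 0.454 after water and 13.8 ± 22.3 after the bacterial spray. PITA_13017 had 2, 436 and 242 reads after the bacterial spray and 1027, 1320 and 1 after water without inoculation, and 345, 384 and 386 against 0 under the nematode. The call on PITA_24346 ended without replicate 3 of the bacterium-sprayed uninoculated group (adjusted p = 1.00), and that on PITA_13017 with voom and 1 weight per group (adjusted p = 0.105), TPM (adjusted p = 0.0510) and a pseudocount of 0.1 (adjusted p = 0.0509). Of the calls 58.8% were higher with TMM, 49.0% with total counts, 43.7% with TPM and 45.2% with quantile normalization, the last 2 of which moved the median gene by -0.21 and -0.15.

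Mock-inoculated seedlings were compared with uninoculated ones, both after the water spray. Any difference in sampling between these groups is part of the comparison and cannot be told apart from mock inoculation. The uninoculated libraries are also the reference of the spray without inoculation. Across genes r between the 2 sets of fold changes was 0.320. Of the calls, 374 were higher in both, against 129 for independent lists, 203 lower in both, against 89.3, and 156 in opposite directions. Part of the excess may come from the shared libraries. Xyloglucan endotransglucosylases rose in 44 and fell in 4 of 64 genes, at 1.32 ± 0.08 log2 CPM with mock and -1.27 ± 0.07 without (SD, n = 3; median 3.60, or 2.79 at the bounds and 1.09 over near-identical groups). Lipoxygenases fell in 25 and rose in 4 of 40 genes, at 3.17 ± 0.02 against 4.62 ± 0.19 (median -1.41, or -0.85 over near-identical groups). AP2/ERF factors rose in 35 and fell in 7 of 61 genes, and class III peroxidases rose in 41 and fell in 8 of 76. R2R3 MYB transcription factors rose in 32 and fell in 9 of 85 genes, and UDP-glycosyltransferases rose in 45 and fell in 14 of 143. Adjusted p-values with an estimated correlation were 0.00215, 0.000652, 0.0131, 0.00215, 0.0131 and 0.0131, in this order. The glycosyltransferase call ended with 1 gene per near-identical group (adjusted p = 0.0551). J-domain co-chaperones rose in 40 and fell in 6 of 75 genes (adjusted p = 0.0985 with an estimated correlation). Chlorophyll a/b-binding proteins fell in 15 and rose in 1 of 28 (adjusted p = 0.188 with an estimated correlation).

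This comparison called 10860 genes, 5569 higher and 5291 lower with mock, 5594 of them by at least 2-fold. PITA_33567 (scaffold115311, 254565 to 256646) had 101 ± 7.76 RPKM (SD, n = 3) with mock and 2 reads in total without inoculation, a ratio of 6475 with a counting interval from 1792 to 53470 (adjusted p = 1.58e-09). It had 4.49 ± 0.47 RPKM with bacterium and nematode and 2, 2 and 3 reads with water and nematode. PITA_03609, which was at 0 with water and nematode, was at least 381-fold higher with mock (adjusted p = 3.79e-07). PITA_40236 (scaffold113426, 11097 to 14925) had 2, 716 and 21 reads without inoculation and 0 with mock, at least 288-fold lower (adjusted p = 0.00710). PITA_23750 (super833, 1239 to 1746) had 22, 2 and 1882 reads against 1 in total, a ratio of 2185 with a counting interval from 391.8 to 86360 (adjusted p = 0.00456; 0.0523 with limma on log2 RPKM and 0.0741 with a pseudocount of 1). The groups compared also differ in spread, 44.1% against 6.04%. Fitting only these 2 groups gave 6865 genes. Of the calls 51.3% were higher with TMM, 48.9% with DESeq2 on the same genes, 49.3% with median-ratio size factors, 45.0% with quantile normalization, 64.2% with log2 RPKM and 61.7% with TPM, the last 2 of which moved the median gene by 0.12 and 0.11.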

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

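Chosen only after the results were seen were the tests of near-identical copies, of scaling and of differences between single seedlings; the splits were set before.

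The spray effect with nematode was tested against that without it, and results past that test are given here as differences between the states. These states differ in inoculation itself as well as in the nematode, since no bacterium-sprayed group had mock inoculation. The count was 5421 genes. Family medians differed by 4.28 for xyloglucan endotransglucosylases, 3.80 for TIFY proteins, 1.33 for HSP20, 0.95 for Aux/IAA proteins and -3.80 for chalcone and stilbene synthases, on the log2 scale. With an estimated correlation only the first passed (adjusted p = 0.0123), and the others had adjusted p = 0.464, 0.0804, 0.0804 and 0.425. Fitted differences were 13.69 for PITA_13017, 12.14 for PITA_23095, -12.73 for PITA_14637 and -12.69 for PITA_24346. Of 100 splits of the spray labels within each state, 5 gave as many genes, the real one included, so chance is not excluded. The highest other gave 9416. The 11 splits that left the nematode groups as labelled, the real one among them, gave 4578 to 9416, and the other 89 gave 0 to 3. Among the splits drawn, the count was thus above 3 only where the nematode groups were as labelled, and there it varied with the division of the uninoculated libraries. Splits that mixed the nematode groups moved any difference between these groups into the spread, whatever its source.

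Xyloglucan endotransglucosylase, TIFY and AP2/ERF genes were higher under the nematode after the bacterial spray, though the TIFY call did not hold with an estimated correlation (adjusted p = 0.207). Near-identical copies counted many times do not account for this, since the smallest of the 3 medians over near-identical groups was 2.41 on the log2 scale. Scaling does not account for all of it, since quantile normalization, which moved the median gene by -0.17, left medians of 3.22, 2.67 and 1.89 over the 50, 30 and 45 members past its RPKM filter, against 3.48, 2.92 and 2.13 for RPKM with TMM factors. Differences between single seedlings stay open, and the range of the family mean over the 6 uninoculated libraries, as a share of the difference under the nematode, was 0.129 for xyloglucan endotransglucosylases, 0.466 for AP2/ERF and 0.614 for TIFY. A response to the spray under the nematode may also account for the pattern, and the labels do not tell how many seedlings each library holds, so these cannot be told apart.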

How the results depend on the processing

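Chosen only after the data were seen were voom with 1 weight per group, the log2 limit on fits of only the groups compared, 1 gene per near-identical group, the added scalings, DESeq2 with the count filter and the divided mock libraries. Some family medians changed sign, as given with each family, as did the majority of higher or lower calls in some comparisons, while no family test and no named gene changed direction. Of the values for families 842 kept their side of the threshold and 51 lost it, and of those for named genes 494 and 38. Results are given in the order spray without inoculation, nematode against mock, spray under the nematode, spray and nematode against mock, difference of spray effects, mock against uninoculated. The counts 1146, 4757, 9543, 6191, 5421 and 10860 became 743, 2285, 4034, 2785, 2700 and 4453 with RPKM of at least 5 in 3 libraries, where fewer genes are tested. A change of at least 1 on the log2 scale left 699, 2592, 5575, 3877 and 5594 for all but the difference. Only the groups compared gave 0, 12027, 15266, 13112 and 6865, again without the difference, and with the log2 limit 0 for the first, 6181 for the third, 3291 for the difference and 4126 for the last. Voom gave 54, 11717, 15214 and 12806 for the first 4. DESeq2 gave 2496 for the first with no count filter and 2517 with the filter kept. TPM gave 3159 for nematode against mock and 6763 for mock against uninoculated, where log2 RPKM gave 7104, or 7062 and 7106 with pseudocounts 0.1 and 1. The cause was not tested. Leaving out 1 library gave 525 to 6342, 2920 to 3094, 7374 to 7608, 4346 to 4549, 4070 to 7008 and 8478 to 11408. Replicate numbers did not pair the libraries (30 pairs, r -0.125 to 0.0425, 2 of the 15 libraries correlating best with one of their own number, 0 of them in every other group), and the replicate block moved the first count to 607, no other by over 1.5 times, and ended the calls on PITA_04436 and PITA_47475 (adjusted p = 0.0568 and 0.0531). The correlation of spray effects with and without nematode, 0.147, was 0.253 over genes above the median level and 0.0867 to 0.201 with 1 library left out. The 1002 genes shared by the comparisons with mock were 552 with the log2 limit and 556 to 721 with 1 library left out. With the mock libraries divided between both comparisons, where each has fewer, they were 235, 228 and 282 with replicate 1, 2 or 3 alone in nematode against mock and 336, 327 and 339 with it alone in the other. With an estimated correlation 14, 15, 24, 24, 21 and 16 families became 3, 2, 3, 6, 1 and 6, and with 1 gene per near-identical group the first became 9 and the last 8. Leaving out 1 library gave 13 to 17, 14 to 16, 22 to 24, 23 to 25, 16 to 24 and 16 to 19 families. Total counts moved the median gene of the difference by -0.10. At these depths and this spread a 2-fold change was recovered in 53.7%, 33%, 33.7%, 34.3%, 12% and 43.7% of simulated changed genes, all of them above a minimum expected count.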

Other observations

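Chosen only after the results were seen were the test of library depth, the counts by comparison and by copy, and the families described first; the tests of an aberrant library, of genotype, of the spray and the splits were set before.

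Other defence families also differed under the nematode between the sprays, at the preset correlation. Of 88 beta-1,3-glucanase genes (PR-2), 39 rose and 3 fell after the bacterial spray, from 0.61 ± 0.09 to 1.45 ± 0.06 log2 CPM (SD, n = 3; median 0.74, or 0.56 over near-identical groups; adjusted p = 0.513 with an estimated correlation). Of 49 glycoside hydrolase 19 chitinases (PR-3), 22 rose and 0 fell, from 0.43 ± 0.09 to 1.83 ± 0.06 (median 1.33, or 1.14 over near-identical groups; adjusted p = 0.513 with an estimated correlation). Both enzymes cut fungal wall polymers. Of 58 NB-ARC disease resistance genes, which encode intracellular immune receptors, 20 rose and 3 fell (median 0.51, or 0.39 over near-identical groups; adjusted p = 0.513 with an estimated correlation). The NB-ARC call also ended with 1 gene per near-identical group (adjusted p = 0.138). Not every defence family rose. Bet v 1-like proteins (PR-10) went from 3.08 ± 0.13 to 2.63 ± 0.09 log2 CPM. Of their near-identical groups 2 held a gene that rose and 4 one that fell (median over groups -0.67). Thaumatin-like proteins (PR-5) went from 0.35 ± 0.01 to 0.15 ± 0.05, with 6 such groups higher and 4 lower (median over groups 0.44).

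Against mock, bacterium-sprayed seedlings with nematode had 23 of 113 terpene synthase genes lower and 5 higher (median -0.32, or -0.79 over near-identical groups; adjusted p = 0.118 with an estimated correlation). Terpene synthases make the terpenes of pine resin. Of 339 cytochrome P450 genes 82 were lower and 20 higher (median -0.36; adjusted p = 0.136 with an estimated correlation). Between mock and uninoculated seedlings, 18 of 24 Bet v 1-like genes (PR-10) rose and 2 fell (median 1.76; adjusted p = 0.188 with an estimated correlation). Rubisco small subunits, of the carbon-fixing enzyme, fell in 8 of 10 genes and rose in 0, from 10.44 ± 0.35 to 9.69 ± 0.13 log2 CPM (median -0.92, or -0.59 over 4 near-identical groups; adjusted p = 0.426 with an estimated correlation).

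The spread between replicates was 5.58% to 6.34% in the inoculated groups and 32.7% and 44.1% in the uninoculated ones. Depth does not account for this, since the ratio of median totals, inoculated to uninoculated, was 0.978, nor does a single aberrant library, since the smallest coefficient in an uninoculated group with 1 library left out was 0.273. Genes with at least 200 reads in a library of the group and an 8-fold range between replicates were counted. They numbered 221 and 410 in the uninoculated groups and 0, 1 and 0 in the inoculated ones, which restates the spread. Chi-square per gene of replicate counts against counting noise, where 1 is counting alone, was 1.93 to 4.63 in the inoculated groups. In the uninoculated groups it was 24.5 to 86.1. For genes with 20 to 99 reads in a pair it was 1.33 to 1.53 and 4.24 to 7.63. Inoculated replicates were thus far nearer to counting noise, which does not tell what they shared. Whether the libraries of an inoculated group share their source material stays open, since the labels do not say. If they do, p-values among the inoculated groups would not cover differences between seedlings.

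Some genes had at least 200 reads in every library of an inoculated group and 0 in every library of another. They numbered 4, 6 and 4 in the comparisons of nematode with mock, of the sprays under the nematode and of spray and nematode with mock. A genotype difference between seedlings may account for such genes, and of the 10 distinct ones 4 were also on in some and off in other uninoculated libraries, against 1 of 100 genes matched on abundance, a ratio of 40. This met the bound set beforehand for genotype, but after the values were seen it was read as undecided, since by comparison the counts were 0 of 4, 1 of 6 and 4 of 4, near-identical copies reduce the 4 to 3 and the 10 to 8, and PITA_16153 had 231, 101 and 112 reads after the bacterial spray and 24, 0 and 0 after water. Among the uninoculated libraries these counts took at least 50 reads as on and exactly 0 as off. They thus leave out PITA_13017 of the comparison of sprays. Without inoculation it had 2, 436 and 242 reads after the bacterial spray and 1027, 1320 and 1 after water. For the spray as the cause, the median spray effect without inoculation, signed by the direction under the nematode, was -0.385 (bootstrap 95% interval -2.14 to -0.30), which met the bound set beforehand against the spray, an upper end under 0.5, but only 3 genes had enough reads, and a minimum number was required only after the value had been seen. The spray and genotype therefore cannot be told apart for PITA_13017, PITA_23095 and PITA_47643 of the comparison of sprays. PITA_08108, PITA_36003 and PITA_42480 of that comparison are also among the 4 of nematode against mock. Those 4 differed between groups that both received water, a difference that the spray cannot account for. No value here bears out genotype for them.

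Of 10 splits of the 6 libraries of each comparison, too few for a share under 0.05, 2 gave as many genes as the labelled groups for the spray without inoculation, the real one included, and 1 for each other comparison. For the spray without inoculation the real count was 1146 and the highest other 3831, which joins replicates 1 and 2 of the bacterial group with replicate 3 of the water group and points to a structure of these libraries other than the labels. For nematode against mock the counts were 4757 and 0, for the sprays under the nematode 9543 and 0, for spray and nematode against mock 6191 and 0, and for mock against uninoculated 10860 and 0. The other splits mix the labelled groups, so any difference between those groups, whatever its source, enters the spread. Counts of 0 therefore cannot tell an effect of treatment from another difference between the groups.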
